A study of Homo sapiens with 6 samples.

How the data were processed

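Bulk RNA sequencing was made from 2 kinds of T cell sorted from human peripheral blood, with 3 libraries of each. These were CD4 T cells and MAIT (mucosal-associated invariant T) cells. Per the labels' protocols, CD4 T cells were gated as CD45 and CD4 positive, and MAIT cells as CD45 and CD3 positive cells that bound an MR1 tetramer loaded with 5-OP-RU, a riboflavin-derived antigen. Per the same protocols, cells were pooled per sample and sorted into Trizol LS, and libraries followed standard Illumina protocols.

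The authors deposited 1 table of raw read counts per gene, with 1 column for each of the 6 libraries and 66023 gene IDs. Per the submitters' processing notes, bcl2fastq 2.20.0.422, FastQC 1.0.0, STAR 2.5.3a, Cufflinks 2.0 and DESeq2 1.1 were used, and the build is given as mm10. The gene IDs in the table are human Ensembl IDs, although mm10 is a mouse build. The role of each tool, the read counter, its strand setting, the annotation release and any filter are not given in the sources used here. The values were whole numbers with a different total in each library, and the table ended in 2 lines that name no gene. These count reads on no annotated feature, 51.8% to 54.3% of all counted reads per library, and reads that were ambiguous between genes, 1.90% to 2.30%. Both were kept out of library sizes and tests.

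Gene symbols and coordinates (GRCh38) were taken from GENCODE release 29, which held 56927 of the IDs. The build on which the reads were counted is not settled by the sources, so the coordinates describe the gene IDs and not the alignments. Total counts on genes ran from 11949848 to 15782966 per library. At that depth 3 counts equal 0.190 to 0.251 CPM (counts scaled to library size) in 1 library. Over the 3 libraries of a group, 3 counts equal 0.0784 CPM in CD4 T cells and 0.0748 CPM in MAIT cells, and this was the floor for a gene with 0 counts in a group. Fold limits were computed from the summed counts of the higher group against that floor, so they describe the group and not each library. For a gene with 1 to 3 counts in a group, the ratio is given with a 95% exact binomial (Clopper-Pearson) counting interval. Floors and intervals cover counting error only.

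The comparison of MAIT cells with CD4 T cells used edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values (TMM) scaling, filterByExpr by group (minimum count 10, minimum total 15), a quasi-likelihood fit and its F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are MAIT over CD4. Mean CPM and SD are over the 3 libraries of a group, on TMM-scaled library sizes. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic. It restates that test and is not a separately estimated standard error. The gene lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the 25 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Camera compares the genes of a list with all other genes. The fry p-value tests whether the genes of a list move, on balance, one way, and compares them with no other genes.

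The comparison, its tests, the 31 gene lists, the rule for naming genes and all but 3 of the alternative settings were chosen before the data were examined. The rule named the 12 genes with the largest log2 fold change in each direction among those past the threshold, with no overlap between the groups and a mean of at least 10 CPM in the higher group. It also named every member of the lists MAIT identity, sorting gate, and CD8 and double-negative T cells. From each other list it named up to 4 members with the smallest adjusted p and any member called against the direction of most called members. The rule gave 151 genes. The other lists covered naive and central memory, cytotoxic granule, NK receptors, the type 17, type 1 and type 2 programs, regulatory T cell, follicular helper, chemokine and homing receptors, cytokine receptors, innate-like T cell transcription factors, exhaustion and checkpoint, tissue repair, immediate early and sort stress, interferon-stimulated, proliferation, glycolysis, oxidative phosphorylation, mitochondrially encoded and ribosomal protein genes. Markers of B cells, monocytes, dendritic cells, NK cells, gamma-delta T cells, platelets, erythroid cells and granulocytes made up the rest. A gene could be in more than 1 list.

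A set of 1161 genes that differ between people, among them sex-linked, HLA and KIR genes and genes with common whole-gene deletions, was left out of every test and correlation. These took 2.04% to 2.87% of gene counts per library.

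The alternative settings were the Wald test of DESeq2 1.42.0, DESeq2 size factors, upper-quartile scaling, no filter on low counts, at least 5 CPM in 3 libraries, the replicate number as a block, limma-voom, a table without mitochondrial, ribosomal protein, T cell receptor and immunoglobulin genes, each of the 6 libraries left out in turn, an adjusted p of 0.01, and a test against a 2-fold threshold. The 3 settings added after seeing the data were an offset per gene and library from a smooth fit on GC content and exonic length (mgcv 1.9.3, 14416 genes with both values), a table without genes for which a partner on the opposite strand could give at least 25% of the counts, and robust empirical Bayes moderation. Overlaps between genes were found with bedtools 2.31.1. As the strand setting of the counter is not given, reads from a gene and its antisense partner cannot be told apart, and genes that share sequence with a close copy, such as T cell receptor variable genes and ribosomal protein genes with pseudogenes, are uncertain to the extent that reads were split between copies. The table was prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

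The libraries were checked for duplicates. Spearman correlations across genes, which are not independent replicates, were 0.902 to 0.935 within groups and 0.805 to 0.888 between groups. No 2 libraries were near-copies, since the lowest chi-square per gene with at least 20 counts was 34.1 within a group. On a principal component plane, the 1st component held 42.3% of the variance and parted the groups, and the 2nd held 18.9%.

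The tests were run on simulated data with the libraries' own means and depths and the dispersions that edgeR estimated from them. There were 14530 genes, and 200 genes were changed, 50 at each fold. edgeR called 8% of the genes changed 2-fold, 46% of those changed 4-fold, 62% at 8-fold and 68% at 16-fold, with 0 of the wrong sign, and 4 of 14310 unchanged genes. DESeq2 called 24%, 72%, 76% and 82%, with 59 unchanged genes, or 30.9% of its calls. voom called 6%, 44%, 48% and 50%, with 3 unchanged genes. Camera called the 1 changed list of 20 genes and 0 of the other lists. The simulated genes were drawn independently of each other. The simulation thus could not show false list calls that come from correlation between genes. A GC trend put into the simulated counts had a Spearman correlation with log2 fold change of -0.66 before the offsets and -0.012 after.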

Results

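Gene counts were obtained for 6 libraries of T cells sorted from human peripheral blood, 3 of CD4 T cells and 3 of MAIT cells. CD4 T cells are the conventional helper lineage, and MAIT cells are innate-like T cells that recognise riboflavin-derived antigens on the MHC-like protein MR1. The CD4 libraries held 15782966, 13046314 and 11949848 counts on genes (replicates 1 to 3), and the MAIT libraries held 13615379, 12440044 and 13859425. Between 17354 and 20000 genes had at least 1 count per library. No label says that the replicates came from separate donors, so p-values measure only the spread between these samples, which may be technical.

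The comparison asked how the transcriptome of circulating MAIT cells differed from that of circulating CD4 T cells. MAIT cells carried more RNA for their own receptor chain, for the transcription factors of innate-like T cells, and for some receptors of inflammatory cytokines. They also carried more RNA for the CD8 co-receptor, for NK receptors and for several granule proteins. CD4 T cells carried more RNA for the CD4 co-receptor, for a lymph node homing receptor, for FOXP3 and for most ribosomal proteins tested. As lists, cytokine receptors, granule, regulatory T cell and ribosomal protein genes were called by camera with its preset correlation but not with an estimated one (adjusted p = 0.0819, 0.199, 0.169 and 0.0985).

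Of 14530 genes tested with edgeR, 1103 differed (7.59%), with 597 higher in MAIT cells and 506 lower, and 3257 genes had an unadjusted p under 0.05. At least 2-fold differences numbered 847, of which 545 were higher and 302 lower. The groups did not overlap for 4605 genes, or 31.7%, where chance gives 10% for 3 libraries against 3. When any 1 of the 6 libraries was left out, the number of genes fell to between 451 (without CD4 replicate 2) and 724 (without CD4 replicate 3), and 425 to 633 of these were among the 1103, all with the same sign. Such a refit has fewer residual degrees of freedom and less power, whichever library is left out. A call lost in it therefore does not by itself show that the call rested on that library. The number with at least 2-fold differences was 369 without CD4 replicate 2, 387 without MAIT replicate 2, 419 without MAIT replicate 1 and 529 without CD4 replicate 1. Genes higher in MAIT cells made up 54.1% of the calls with TMM scaling, 43.2% with upper-quartile scaling, which moved the median log2 fold change of all genes by -0.12, and 42.4% after a correction for GC content and length. Among the 1103 genes, 121 had 0 counts in 1 group, and 67 overlapped a gene on the opposite strand that could give at least 25% of their counts.

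**Figure D1:**
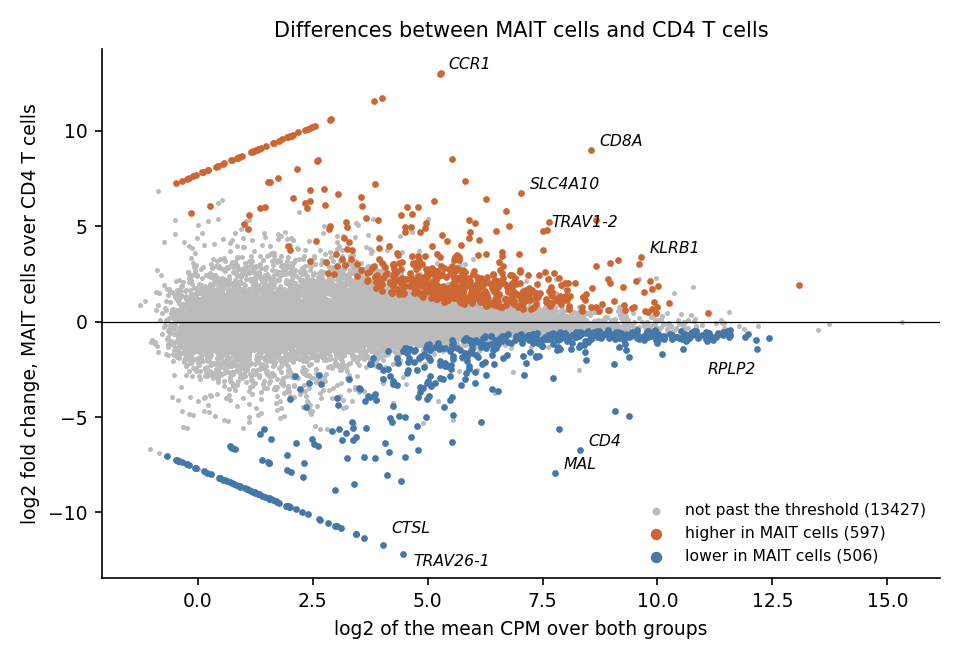
Each point is 1 of the 14530 genes tested, with the log2 of its mean CPM over both groups on the horizontal axis and its fitted log2 fold change of MAIT over CD4 T cells on the vertical axis, in colour for the 597 genes higher and the 506 lower in MAIT cells. The streaks at the upper and lower edges are genes with 0 counts in 1 group, whose fitted fold depends on the prior count and is no estimate of size.

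The genes of the sorting gates came first, since they check the labels. CD4 (ENSG00000010610.9, chromosome 12, 6786858 to 6820808), the co-receptor used for sorting, was at 630 ± 36.3 CPM in CD4 T cells and 5.90 ± 5.71 CPM in MAIT cells (SD, n = 3). Its log2 fold change was -6.73 (SE 0.84, edgeR adjusted p = 0.00428). CD8A (ENSG00000153563.15, chromosome 2, 86784610 to 86808396) and CD8B (ENSG00000172116.21, chromosome 2, 86815339 to 86861924) encode the co-receptor of class I-restricted T cells. CD8A was at 1.45 ± 1.49 CPM in CD4 T cells and 748 ± 20.1 in MAIT cells, a log2 fold change of 8.98 (SE 0.73, edgeR adjusted p = 0.00104). CD8B was at 0.666 ± 0.600 and 111 ± 29.7 CPM, a log2 fold change of 7.35 (SE 0.64, edgeR adjusted p = 0.00131). Both CD8 genes were higher over all genes and adjusted over the list alone, a list too short for camera. PTPRC (ENSG00000081237.18, chromosome 1, 198638457 to 198757476), the CD45 antigen of both gates, was at 170 ± 55.6 and 796 ± 322 CPM, a log2 fold change of 2.23 (SE 0.34, edgeR adjusted p = 0.00917) that became 1.46 after the correction for GC content and length (edgeR adjusted p = 0.0204). Of the CD3 chains of the receptor complex, CD3G was lower by a log2 fold change of -0.43 (edgeR adjusted p = 0.0498), a call that ended when any 1 of the 6 libraries was left out (0.0970 to 0.171), with the replicate block (0.0994), with no filter (0.135) and in the table without ribosomal and receptor genes (0.0556). CD3D (-0.36, edgeR adjusted p = 0.0506), CD3E (-0.15) and CD247 (-0.22) were not past the threshold, although CD3D passed under 7 alternatives (0.00199 to 0.0493). The sorting gate list thus had 1 member higher and 2 lower of 6, with 1 higher and 3 lower adjusted over the list alone, and 1 lower when any 1 of the 6 libraries was left out. Camera did not call it (adjusted p = 0.127, 0.255 with an estimated correlation), except without MAIT replicate 2 (adjusted p = 0.00318) and with voom (adjusted p = 0.0164).

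Genes known as marks of MAIT cells set the groups apart. Of the 24 genes in the MAIT identity list, 19 were higher in MAIT cells and 0 lower, and 24 were higher adjusted over the list alone. The median log2 fold change was 4.32, and camera gave an adjusted p of 1.03e-67 (0.00318 with an estimated correlation). TRAV1-2 (ENSG00000256553.1, chromosome 14, 21642889 to 21643578), the variable segment of the semi-invariant alpha chain, was at 13.2 ± 5.22 CPM in CD4 T cells and 353 ± 22.1 in MAIT cells. Its log2 fold change was 4.75 (SE 0.30, edgeR adjusted p = 0.00032). SLC4A10 (ENSG00000144290.16, chromosome 2, 161424332 to 161985282), a bicarbonate transporter known as a MAIT cell marker, was at 2.44 ± 1.1 and 261 ± 52.3 CPM, a log2 fold change of 6.73 (SE 0.39, edgeR adjusted p = 0.000283). KLRB1 (ENSG00000111796.3, chromosome 12, 9594551 to 9607886), which encodes the surface marker CD161, was at 142 ± 52.0 and 1460 ± 201 CPM, a log2 fold change of 3.36 (SE 0.27, edgeR adjusted p = 0.00104). ZBTB16 (ENSG00000109906.13, chromosome 11, 114059593 to 114250676), which encodes the innate-like factor PLZF, was at 6.65 ± 2.60 and 213 ± 17.5 CPM, a log2 fold change of 5.00 (SE 0.32, edgeR adjusted p = 0.00032). CXCR6 (ENSG00000172215.5, chromosome 3, 45940933 to 45948353), a tissue homing receptor, had a log2 fold change of 5.22 (SE 0.44, edgeR adjusted p = 0.00114). NCR3 (ENSG00000204475.9, chromosome 6, 31588895 to 31592985), the activating receptor NKp30, had one of 5.31 (SE 0.28, edgeR adjusted p = 0.000152). PRSS35, a serine protease, had 0 counts in the CD4 libraries and was at least 418-fold higher (edgeR adjusted p = 0.00428).

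The multidrug transporter ABCB1 (log2 fold change 4.56), the surface protease gene DPP4 (2.55), the kinase LTK (3.48) and the inhibitory receptor KLRG1 (2.91) were higher as well, at an adjusted p of 0.05 in every refit and with any 1 library left out. The acetylcholinesterase anchor COLQ (4.26, edgeR adjusted p = 0.0416) did not pass with the replicate block (0.0633), nor without CD4 replicate 3 or MAIT replicate 1, 2 or 3 (0.0997 to 0.108). The 5 members not past the threshold were CCR6, IL12RB2, TLE1, B3GALT2 and ME1, each with a fitted value above 0. Without CD4 replicate 1, IL12RB2 (0.0289), TLE1 (0.00204) and B3GALT2 (0.0121) passed, and without CD4 replicate 3, ME1 did (0.0250). With no filter, IL12RB2 (0.0454), TLE1 (7.36e-05), B3GALT2 (0.00473) and ME1 (0.000742) passed. DESeq2 called B3GALT2 (0.00325) and ME1 (0.000509), and at least 5 CPM in 3 libraries let TLE1 (0.0322) and ME1 (0.0427) pass. TLE1 also passed with voom (0.0324), after the correction for GC content and length (0.0496) and without genes under an opposite-strand partner (0.0479).

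**Figure D2:**
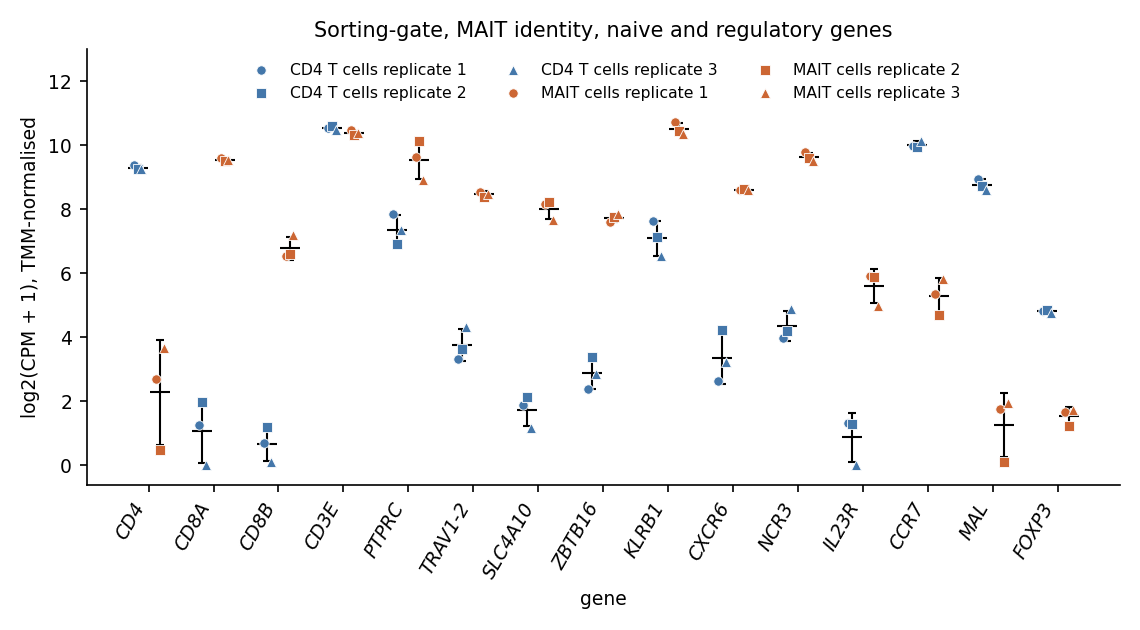
Each point is 1 library, with log2(CPM + 1) on the vertical axis and genes along the horizontal axis, CD4 T cells in blue and MAIT cells in orange, and the black bar is the mean with the SD of the 3 libraries of a group on that scale. CD4 separates the groups in one direction (630 against 5.90 CPM) and CD8A in the other (1.45 against 748 CPM).

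Besides CD8A, the genes named by the size of their fitted fold had 0 counts in 1 of the groups. Higher in MAIT cells were PIK3AP1 (ENSG00000155629.14, chromosome 10, 96593312 to 96720514), an adaptor that couples receptors to PI3 kinase, and CCR1 (ENSG00000163823.3, chromosome 3, 46201709 to 46208396), an inflammatory chemokine receptor. PIK3AP1 had 0 counts in the CD4 libraries and 78.6 ± 22.3 CPM in MAIT cells, at least 998-fold higher (edgeR adjusted p = 0.00104). CCR1 had 0 counts and 77.7 ± 18.4 CPM, at least 991-fold higher (edgeR adjusted p = 0.00092). The matrix protein gene MATN2 (ENSG00000132561.13, chromosome 8, 97868840 to 98036716) was at least 362-fold higher (edgeR adjusted p = 0.0034). Also 0 in CD4 T cells were the phospholipase gene PLD1 and the secreted WNT modulator DKK3 (each at least 190-fold higher), TMEM182 (148), RP11-148O21.4 (144, with no match in the annotation), the receptor kinase ROR2 (142), the cannabinoid receptor CNR2 (137) and the repressor GFI1B (127). With the replicate block these 7 genes had adjusted p of 0.0516 to 0.0702 and did not pass, and with voom PLD1, DKK3, ROR2 and CNR2 did not (0.0602 to 0.154). When 1 library was left out, PLD1 was lost without MAIT replicate 2 (0.0524), CNR2 without CD4 replicate 2 or MAIT replicate 1 or 3 (0.0572, 0.0680 and 0.0664), and ROR2 in all cases (0.0705 to 0.114) except without MAIT replicate 2. In MAIT replicates 1 to 3, ROR2 was at 27.1, 1.25 and 4.44 CPM and CNR2 at 10.8, 1.95 and 18.8 CPM. Their fold limits therefore do not hold for each library.

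Lower in MAIT cells was TRAV26-1 (ENSG00000211807.3, chromosome 14, 22123318 to 22124285), another alpha chain variable segment, at 43.9 ± 2.54 CPM in CD4 T cells and 0 counts in MAIT cells, at least 590-fold lower (edgeR adjusted p = 0.00112). CTSL (ENSG00000135047.14, chromosome 9, 87725519 to 87731393), the lysosomal protease cathepsin L, was at least 419-fold lower (edgeR adjusted p = 0.00331), and the solute carrier gene SLC22A17 (ENSG00000092096.14, chromosome 14, 23346306 to 23352912) was at least 332-fold lower (edgeR adjusted p = 0.00313). Other genes with 0 counts in MAIT cells were WNT7A and CDCA7L (each at least 281-fold lower), the dynein gene DNAH6 (222), the somatostatin receptor gene SSTR3 (217), AC020571.3 (216), the RhoA exchange factor NET1 (194), C2orf40 (171), ZNF667-AS1 (161) and the hair cell gene TMIE (131). With the replicate block, NET1, C2orf40, ZNF667-AS1 and TMIE did not pass (adjusted p 0.0557 to 0.0670), and with voom WNT7A, NET1, ZNF667-AS1 and TMIE did not (0.0913 to 0.125). When 1 library was left out, NET1 (0.0521 to 0.0723, all cases except without CD4 replicate 3), ZNF667-AS1 (0.0530 to 0.0580, without CD4 replicate 1 or 3 or MAIT replicate 1 or 2) and TMIE (0.0532 to 0.0643, without CD4 replicate 2 or 3 or MAIT replicate 1 or 2) lost their calls.

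Transcription factors of innate-like T cells were mostly higher in MAIT cells. Of 21 tested, 13 were higher and 1 lower, with 15 higher and 2 lower adjusted over the list alone, and camera gave an adjusted p of 4.01e-18 (0.0262 with an estimated correlation). ZBTB16, EOMES and CEBPD were among them. EOMES (ENSG00000163508.12, chromosome 3, 27715949 to 27722711), a T-box factor of effector and memory cells, was at 25.5 ± 10.9 CPM in CD4 T cells and 339 ± 44.9 in MAIT cells (log2 fold change 3.73, SE 0.31, edgeR adjusted p = 0.00114). CEBPD, a C/EBP factor linked to MAIT cell migration, had a log2 fold change of 4.79 (SE 0.42, edgeR adjusted p = 0.00134), and ID2, an inhibitor of E proteins, had one of 1.55 (SE 0.16, edgeR adjusted p = 0.00211). Its counterpart ID3, which keeps lymphocytes in a naive state, was the member lower, at -5.02 (SE 0.86, edgeR adjusted p = 0.0137), and did not pass without MAIT replicate 1 (0.0551). The number lower was then 0, and it was 2 without MAIT replicate 3.

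Type 17 genes were also higher. Of 13 tested, 9 were higher and 0 lower, with 12 higher adjusted over the list alone, and camera gave an adjusted p of 1.90e-14 (0.0262 with an estimated correlation). The number higher was 5 without CD4 replicate 2 and without MAIT replicate 1. BLK, a Src-family kinase found in IL-17-producing T cells, was at 0.263 ± 0.456 CPM in CD4 T cells and 91.8 ± 7.86 in MAIT cells, a log2 fold change of 8.51 (SE 0.92, edgeR adjusted p = 0.00285). The amino acid oxidase gene IL4I1 (3.42) and the cathepsin gene CTSH (1.79) were higher, and the CCR6 ligand gene CCL20, with 0 counts in CD4 T cells, was at least 105-fold higher (edgeR adjusted p = 0.0109, 0.0780 with the replicate block). In the type 1 list, 4 of 14 genes were higher and 0 lower, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.46e-06, 0.111 with an estimated correlation). The 4 were EOMES, IL18RAP, the homeobox cofactor gene HOPX (1.67) and STAT4, which signals for IL-12 (2.26, edgeR adjusted p = 0.0146, 0.0534 without MAIT replicate 2). The number higher was 7 without CD4 replicate 3, and 1 was lower without MAIT replicate 3. In the type 2 list, 4 of 11 genes could be tested and 0 passed by edgeR, DESeq2 or voom, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. GATA3, the master factor of that program, was at nearly equal levels (log2 fold change -0.05).

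Receptors for cytokines separated the cells further. Of 25 tested, 7 were higher and 2 lower in MAIT cells, with 11 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.000917, 0.0819 with an estimated correlation). IL18R1 (log2 fold change 3.55) and IL18RAP (4.39), which form the IL-18 receptor, and IL23R (5.61, SE 0.93, edgeR adjusted p = 0.0122) are shared with the MAIT identity list. IL7R, which takes up the survival cytokine IL-7, was at 442 ± 78.4 and 1626 ± 420 CPM (log2 fold change 1.88, SE 0.22, edgeR adjusted p = 0.00331), and TGFBR3 had a log2 fold change of 3.55 (SE 0.33, edgeR adjusted p = 0.00151). The members lower were IL4R (-2.09, SE 0.32, edgeR adjusted p = 0.00872) and IL17RA (-0.98, edgeR adjusted p = 0.0458). IL17RA did not pass after the correction for GC content and length (0.0554), with the replicate block (0.0514), or without CD4 replicate 1, 2 or 3 or MAIT replicate 1 or 2 (0.0857 to 0.151). The number lower was 1 without CD4 replicate 1, 2 or 3 or MAIT replicate 2.

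CD4 T cells had higher levels of genes of naive and central memory cells. Of 24 such genes, 9 were lower and 1 higher in MAIT cells, with 16 lower and 2 higher adjusted over the list alone, and camera gave an adjusted p of 6.59e-18 (0.00758 with an estimated correlation). CCR7 (ENSG00000126353.3, chromosome 17, 40553769 to 40565472), the chemokine receptor for lymph node entry, was at 1042 ± 78.4 CPM in CD4 T cells and 40.2 ± 15.6 in MAIT cells, a log2 fold change of -4.69 (SE 0.30, edgeR adjusted p = 0.00032). MAL (ENSG00000172005.10, chromosome 2, 95025677 to 95053996), a membrane trafficking protein of resting T cells, was at 437 ± 52.7 and 1.76 ± 1.47 CPM, a log2 fold change of -7.93 (SE 0.70, edgeR adjusted p = 0.00133). TCF7, a factor of naive and stem-like T cells, had a log2 fold change of -1.35 (SE 0.12, edgeR adjusted p = 0.00151). SATB1, a chromatin organiser, was the member higher, at 1.64 (edgeR adjusted p = 0.0144). That call was lost with the replicate block (0.0670), after the correction for GC content and length (0.0575) and without CD4 replicate 1 or 2 or MAIT replicate 1 or 2 (0.0543 to 0.0560), where the number higher was 0.

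Chemokine and homing receptors went both ways. Of 24 tested, 4 were higher and 4 lower in MAIT cells, with 6 higher and 9 lower adjusted over the list alone. The list's median log2 fold change was -0.29 and its mean 0.31, and camera put it lower without passing (adjusted p = 0.122, 0.258 with an estimated correlation), except without MAIT replicate 2 (0.0457) and with DESeq2 (0.00951). Among those higher were CCR1, CXCR6 and CXCR4, the last named after its value was seen (log2 fold change 0.76). Among those lower were CCR7, the integrin chain gene ITGB1 (-1.48, edgeR adjusted p = 0.0111) and the sphingosine receptor gene S1PR4 (-0.68, edgeR adjusted p = 0.0209). S1PR4 did not pass after the correction for GC content and length (0.213) or without CD4 replicate 1, 2 or 3 or MAIT replicate 1 or 2 (0.0553 to 0.0751).

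Granule genes of cytotoxic cells were higher in MAIT cells only in part. Of 15, 5 were higher and 0 lower by edgeR, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.72e-08, 0.199 with an estimated correlation). GZMK (ENSG00000113088.5, chromosome 5, 55024253 to 55034570), a granzyme of memory-like cells, was at 170 ± 38.5 CPM in CD4 T cells and 1385 ± 195 in MAIT cells, a log2 fold change of 3.03 (SE 0.19, edgeR adjusted p = 0.00032). CTSW (2.11, SE 0.25, edgeR adjusted p = 0.00343), a protease of killer cells, and SLAMF7 (3.53, SE 0.52, edgeR adjusted p = 0.00756), a signalling receptor, were higher. GZMA (2.14, edgeR adjusted p = 0.0102) did not pass without CD4 replicate 2 (0.0501), and SRGN (0.89, edgeR adjusted p = 0.0168) was named after its value was seen. The perforin gene PRF1 (2.26, edgeR adjusted p = 0.0505) and CST7 (2.25, 0.0565) missed the threshold, and GZMH and GZMB were lower without passing (-2.54 and -2.63). The spread among CD4 libraries was wide for these genes, with NKG7 at 1166, 820 and 82.6 CPM and GZMH at 924, 617 and 64.4 CPM in replicates 1 to 3. These 5 genes short of the threshold were named after their values were seen. The number higher was 3 without CD4 replicate 2 and 9 without CD4 replicate 3, where 2 were lower.

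**Figure D3:**
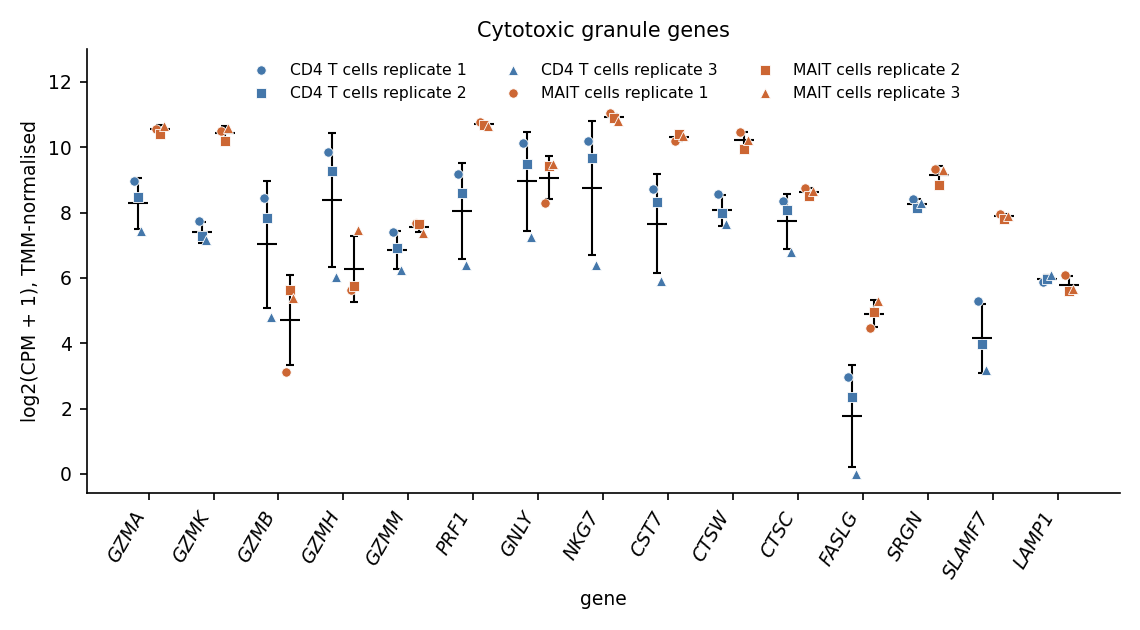
Each point is 1 library, with log2(CPM + 1) on the vertical axis and genes along the horizontal axis, CD4 T cells in blue and MAIT cells in orange, and the black bar is the mean with the SD of the 3 libraries of a group on that scale. The CD4 T cell libraries spread over 14.1-fold for NKG7 and 14.3-fold for GZMH, while CD4 itself spread over 1.11-fold.

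Receptors of natural killer (NK) cells were higher in MAIT cells. Of 11 tested, 4 were higher and 0 lower, with 9 higher adjusted over the list alone (camera adjusted p = 1.24e-15, 0.0288 with an estimated correlation). These were NCR3, KLRG1, CD160, a receptor for HVEM (log2 fold change 6.32, SE 1.01, edgeR adjusted p = 0.0108), and the CD94 gene KLRD1 (4.22, edgeR adjusted p = 0.0493). KLRD1 did not pass with upper-quartile scaling, the replicate block, voom, robust moderation, the GC content and length correction or the table without ribosomal and receptor genes (0.0507 to 0.110), or when any library but CD4 replicate 3 was left out (0.0946 to 0.146). In the list of NK cell markers, 5 of whose 12 genes are also in other lists, 3 of 9 tested were higher and 0 lower, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000917, 0.193 with an estimated correlation). TYROBP, an adaptor for activating receptors, was at 1.81 ± 2.10 and 153 ± 43.7 CPM, a log2 fold change of 6.43 (SE 0.78, edgeR adjusted p = 0.00374). IL18RAP and CLIC3 were the others, and CLIC3 (2.29, edgeR adjusted p = 0.0191) did not pass with the replicate block (0.0698) or without CD4 replicate 2 (0.0745), MAIT replicate 2 (0.0672) or MAIT replicate 3 (0.0574). Without CD4 replicate 3, 1 member was lower, FGFBP2 (adjusted p = 0.00601). It was also lower with DESeq2 (0.00865), no filter (6.94e-05) and at least 5 CPM in 3 libraries (0.0375). Of 5 gamma-delta T cell genes tested, 2 were higher and 0 lower, with 3 higher adjusted over the list alone (camera adjusted p = 0.00029, 0.169 with an estimated correlation, 0.0621 with voom). The constant segment gene TRGC1 (ENSG00000211689.6, chromosome 7, 38257879 to 38265678), which alpha-beta T cells can also transcribe, was at 4.49 ± 2.39 and 117 ± 23.3 CPM (log2 fold change 4.70, SE 0.42, edgeR adjusted p = 0.00147), and its near-copy TRGC2 had a log2 fold change of 2.58 (SE 0.30, edgeR adjusted p = 0.00331).

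Regulatory T cell genes went both ways, with FOXP3 higher in CD4 T cells. Of 13 tested, 4 were lower and 2 higher in MAIT cells, with 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00228, 0.169 with an estimated correlation). FOXP3 (ENSG00000049768.14, chromosome X, 49250436 to 49264826), the lineage factor of regulatory T cells, was at 27.1 ± 0.903 CPM in CD4 T cells and 1.96 ± 0.546 in MAIT cells, a log2 fold change of -3.79 (SE 0.44, edgeR adjusted p = 0.00339). TNFRSF4, the costimulatory receptor OX40, had a log2 fold change of -2.84 (SE 0.25, edgeR adjusted p = 0.00133). The inhibitory receptor genes CTLA4 (-5.57, edgeR adjusted p = 0.0331) and TIGIT (-2.35, 0.0379) were lower, and the Helios gene IKZF2 was higher (3.94, 0.0331), as was LAYN, with 0 counts in CD4 T cells and at least 46.4-fold higher (0.0281). LAYN lost its call when any 1 library was left out, CTLA4 in all cases except without MAIT replicate 3, TIGIT in all except without MAIT replicate 2, and IKZF2 without CD4 replicate 2 or MAIT replicate 1, 2 or 3. The number lower was 2 without CD4 replicate 1, 2 or 3 or MAIT replicate 1. The number higher was 1 without CD4 replicate 1 or 3 and 0 without any of the other libraries. CTLA4, IKZF2 and LAYN were also lost with the replicate block (0.0727 to 0.129), and IKZF2 after the correction for GC content and length (0.0599).

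Follicular helper genes gave 3 lower and 1 higher of 8 tested, with 4 lower and 1 higher adjusted over the list alone. Camera did not call the list (adjusted p = 0.127, 0.255 with an estimated correlation) except with no filter (0.0146). The costimulator gene ICOS was lower (-2.02, edgeR adjusted p = 0.0128), though not without CD4 replicate 2 (0.0526) or MAIT replicate 1 (0.0528). TOX2 had 0 counts in MAIT cells, at least 39.1-fold lower, and POU2AF1 was lower at a ratio of 131 (interval 23.1 to 5216). Both lost their calls when any 1 of the 6 libraries was left out (0.0715 to 0.141) and with the replicate block, and POU2AF1 also with voom (0.0678). The number lower was 0 without MAIT replicate 1 and 1 without any other library. SH2D1A, the adaptor SAP needed by innate-like T cells, was higher (1.33, SE 0.19, edgeR adjusted p = 0.00726). Of 12 exhaustion and checkpoint genes, 2 were higher (CD160 and LAG3) and 2 lower (CTLA4 and TIGIT), the same numbers adjusted over the list alone (camera adjusted p = 0.877, 0.888 with an estimated correlation). LAG3 (2.47, edgeR adjusted p = 0.0196) did not pass without CD4 replicate 1 or MAIT replicate 1, 2 or 3 (0.0521 to 0.0675), where the number higher was 1. The number lower was 0 without CD4 replicate 1, 2 or 3 or MAIT replicate 1, and 1 without MAIT replicate 2 or 3.

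Early response genes were higher in MAIT cells for a few members. Of 24 tested, 5 were higher and 0 lower, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0332, 0.258 with an estimated correlation). DUSP2, a phosphatase that limits MAP kinase signals, was at 110 ± 28.8 and 1024 ± 204 CPM (log2 fold change 3.22, SE 0.24, edgeR adjusted p = 0.000838). DUSP1 (1.82, SE 0.21, edgeR adjusted p = 0.0033) and the activation marker CD69 (1.31, SE 0.19, edgeR adjusted p = 0.00726) were higher, as were IER5 (1.04, edgeR adjusted p = 0.0241) and PPP1R15A, named after its value was seen (0.76, 0.0476). IER5 did not pass with the replicate block (0.0533) or without any library but CD4 replicate 2 (0.0649 to 0.0830), where the number higher was 3, and 1 member was lower without MAIT replicate 3. Camera did not call the list with upper-quartile scaling (0.0789), voom (0.199), the table without ribosomal and receptor genes (0.0709), or without CD4 replicate 1 (0.0738), CD4 replicate 3 (0.0793) or MAIT replicate 3 (0.128). The gates differed, since only MAIT cells were selected by tetramer binding. An effect of staining or sorting on these genes thus cannot be told apart from cell type.

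Interferon-stimulated genes gave 4 higher and 0 lower of 25, with 5 higher adjusted over the list alone (camera adjusted p = 0.0381, 0.169 with an estimated correlation, 0.0711 without CD4 replicate 1 and 0.121 without genes under an opposite-strand partner). The 4 were XAF1 (log2 fold change 2.22), the RIG-I gene DDX58 (2.55), IFI44L (1.60) and IFI44 (1.26), and a gene on the opposite strand could give 50.8% of the XAF1 counts. Their number was 1 without CD4 replicate 1, 2 or 3 or MAIT replicate 1, 0 without MAIT replicate 2 and 2 without MAIT replicate 3. IFI44, DDX58 and IFI44L did not pass with the replicate block (0.0698 to 0.113) or after the correction for GC content and length (0.0644 to 0.298), and IFI44L did not with upper-quartile scaling (0.0529) or no filter (0.0621). Of 15 tissue repair genes, 1 was lower and 0 higher, with 1 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.349, 0.407 with an estimated correlation). The member lower was GPX4, which protects membranes from peroxides (-0.80, edgeR adjusted p = 0.0174), and it did not pass after the correction for GC content and length (0.165) or without MAIT replicate 1 (0.0707) or 2 (0.0710), where the number was 0. The list's median log2 fold change was 0.31. DESeq2 put PDGFA (ratio 101, interval 17.8 to 4031, DESeq2 adjusted p = 0.00837) and FURIN (0.70, DESeq2 adjusted p = 0.0391) higher.

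Ribosomal protein genes were lower in MAIT cells nearly throughout. Of 38, 31 were lower and 0 higher, with 37 lower adjusted over the list alone, and their summed level was 88382 ± 4716 CPM in CD4 T cells and 53433 ± 2234 CPM in MAIT cells. The median log2 fold change was -0.71, and -0.69 after the correction for GC content and length, and camera gave an adjusted p of 8.09e-28 (0.0985 with an estimated correlation). RPLP2 (ENSG00000177600.8, chromosome 11, 809647 to 812880), a protein of the ribosomal stalk, was at 2905 ± 157 and 1430 ± 31.2 CPM (log2 fold change -1.02, SE 0.08, edgeR adjusted p = 0.00101). RPS27 (-0.94), RPS18 (-0.81) and RPS25 (-0.75) were lower at an adjusted p of 0.05 in every refit that kept them. Genes of glycolysis gave 3 lower and 0 higher of 20, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0329, 0.255 with an estimated correlation). LDHB, a lactate dehydrogenase subunit, was at 1674 ± 137 and 516 ± 78.8 CPM (log2 fold change -1.70, SE 0.14, edgeR adjusted p = 0.00104). PKM (-0.66, edgeR adjusted p = 0.0158) and PFKL (-0.81, 0.0196) were also lower. PKM did not pass without CD4 replicate 2 or MAIT replicate 2 or 3 (0.0532 to 0.0695), PFKL passed only without CD4 replicate 1 among the libraries left out, and neither passed with the replicate block (0.0563 and 0.0676). The number lower was 1 without CD4 replicate 2 or MAIT replicate 2 or 3, and 1 member was higher without MAIT replicate 3. Camera did not call glycolysis after the correction for GC content and length (0.0808) or without CD4 replicate 1 (0.0570) or MAIT replicate 2 (0.0978) or 3 (0.126).

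Nuclear genes of oxidative phosphorylation gave 5 lower and 0 higher of 25, with 8 lower adjusted over the list alone (camera adjusted p = 0.000185, 0.268 with an estimated correlation). They were COX6C, COX4I1, COX7C and COX5B of complex IV and UQCRB of complex III, at log2 fold changes of -0.82, -0.66, -0.59, -0.57 and -0.63, and COX5B was named after its value was seen. Their number was 0 without CD4 replicate 1 or 3 or MAIT replicate 1 or 2, 1 without CD4 replicate 2 and 2 without MAIT replicate 3. Of the 13 mitochondrially encoded genes, among them the complex I subunit gene MT-ND5 (log2 fold change 0.87), 0 passed by edgeR, DESeq2 or voom, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.349, 0.780 with an estimated correlation). Of 16 proliferation genes, 0 passed by edgeR, also adjusted over the list alone, or by voom, 1 passed by DESeq2 and 3 had an unadjusted p under 0.05, while camera put the list lower (adjusted p = 0.0144, 0.133 with an estimated correlation, 0.120 with at least 5 CPM in 3 libraries). The replication helicase gene MCM5 had a log2 fold change of -0.55 and the tubulin-binding STMN1 one of -0.46. With edgeR and no filter, and without CD4 replicate 3 or MAIT replicate 1 or 3, 1 proliferation gene was lower.

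Markers of other blood cells were measured as well. Of 12 granulocyte genes, 0 reached the level for testing. Of 10 dendritic cell genes 2 could be tested, of 9 erythroid genes 4 and of 18 monocyte genes 5, and by edgeR or voom 0 passed, also adjusted over the list alone for edgeR. At an unadjusted p under 0.05 were 0 dendritic, 0 erythroid and 1 monocyte gene. With no filter on low counts, edgeR put the dendritic cell gene FCER1A (0.0234) and the granulocyte gene HDC (0.0464) higher in MAIT cells, both named after their values were seen. The monocyte genes summed to 10.8 ± 2.76 CPM in CD4 T cells and 34.1 ± 35.2 in MAIT cells (camera adjusted p = 0.349, 0.614 with an estimated correlation), and S100A9, their calgranulin, was the 1 marker of these lists that passed with DESeq2 (0.0353). Of 3 B cell genes tested, 0 passed by edgeR or voom, and 1 was higher adjusted over the list alone and had an unadjusted p under 0.05. This was MS4A1, the CD20 antigen, at 0.556 and 21.1 CPM, which passed with DESeq2 (0.000918), with no filter (0.00187) and without CD4 replicate 1 (0.0206), and CD79A was lower without MAIT replicate 2 (0.0311). Of 9 platelet genes, 1 was higher and 0 lower, with 2 higher adjusted over the list alone (camera adjusted p = 0.00228, 0.351 with an estimated correlation), and they summed to 236 ± 191 CPM in CD4 T cells and 573 ± 105 in MAIT cells. It was the tubulin gene TUBB1 (3.37, edgeR adjusted p = 0.0326), whose counts could all come from a gene on the opposite strand, and which did not pass with the replicate block (0.0617) or without CD4 replicate 2 or MAIT replicate 1, 2 or 3 (0.0725 to 0.120), where the number higher was 0. GNG11, a G protein subunit gene (1.69, edgeR adjusted p = 0.0590), passed with DESeq2 (0.00245), no filter (0.00672), at least 5 CPM in 3 libraries (0.0412) and voom (0.0329) and without CD4 replicate 1 (0.0308), where 2 platelet genes were higher.

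**Figure D4:**
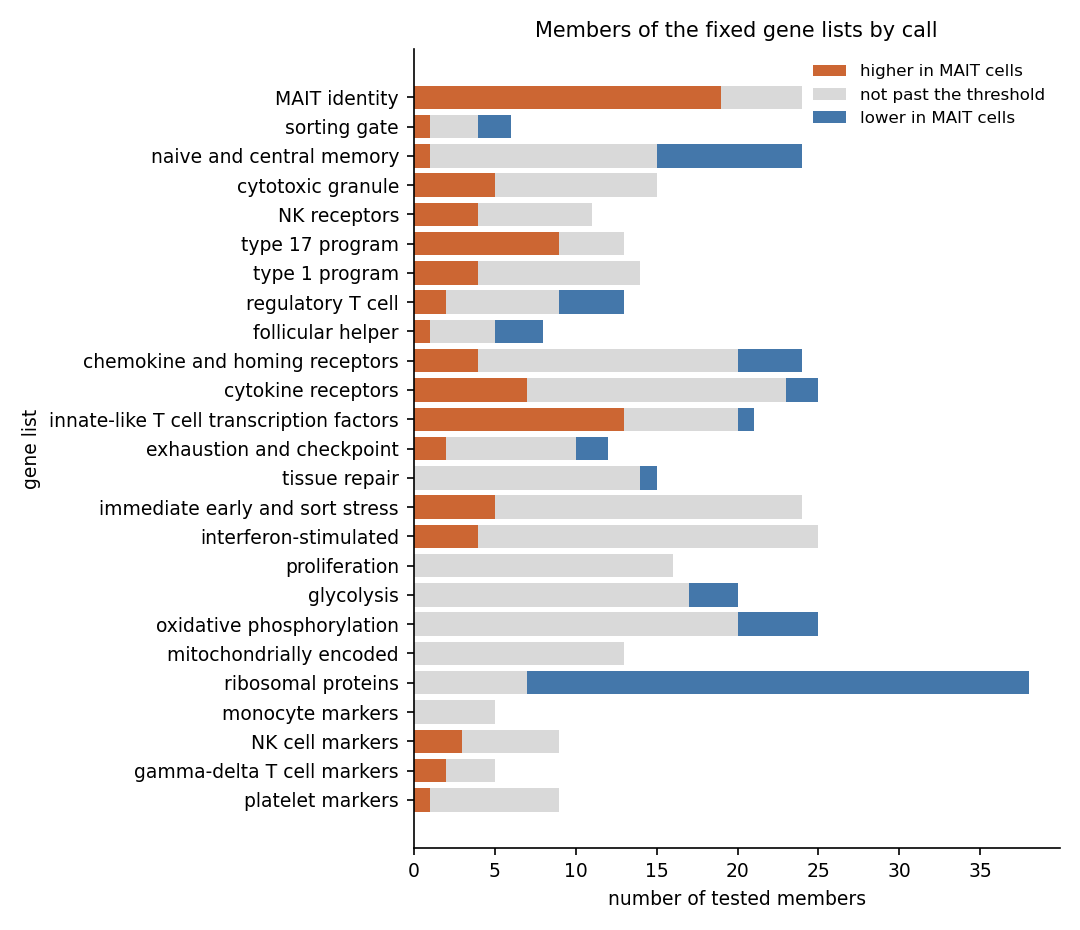
Stacked bars give, for each of the 25 gene lists tested with camera, the number of tested members that were higher, not past the threshold, or lower in MAIT cells at an edgeR adjusted p of 0.05 over all 14530 genes. The MAIT identity list (19 of 24 higher) and the ribosomal protein list (31 of 38 lower) have the most members called in each direction.

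Of the 31 lists, 25 had at least 5 tested members, and camera called 18 of them, 12 higher and 6 lower in MAIT cells. With an estimated correlation 5 were called, namely MAIT identity, NK receptors, type 17 program and innate-like T cell transcription factors, all higher, and naive and central memory, lower. With fry, 20 were called. Of the 151 genes named by the rule, 108 passed the threshold, and 63 of these passed at an adjusted p of 0.05 in every refit of the model that kept them, those with 1 library left out included, while 0 changed sign past the threshold.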

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

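The tests of strand, scaling, NK cells and CD8 T cells were chosen after the results they weigh were seen, and the correction for GC content and length was added after seeing the data.

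Reads on no annotated feature made up 52.6% of all counted reads (mean of the 6 libraries, 52.2 ± 0.351% in CD4 T cells and 53.0 ± 1.21% in MAIT cells, SD, n = 3). They were singled out because the comparisons leave this signal out and it exceeds the limit that a count of 0 allows. Reads of both strands counted on 1 strand could leave such a share, since reads from the other strand would land on antisense genes or on no feature. Over 430 antisense genes with at least 300 counts expected from their partners, the median ratio of observed to expected counts was 1.29 (quartiles 0.605 and 2.18, 1.26 to 1.36 per library), as that explanation needs. Genomic DNA would add reads over silent genes, but 839 olfactory receptor genes held at most 0.0439 of the counts that evenly spread DNA would give (CD4 replicate 3), which argues against DNA as the source. Intronic reads of unspliced RNA were not tested, and the design gives no biological explanation to test.

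Ribosomal protein genes were lower in MAIT cells, with 31 of 38 called and a median log2 fold change of -0.71. Fold changes followed GC content and length across genes with a mean above 10 CPM (Spearman correlations of -0.40 and 0.32), which might lower short, GC-rich genes. After the correction these were 0.038 and -0.024, while the list's median was -0.69 (quartiles -0.84 and -0.53) and 32 of 38 genes were lower, which argues against that trend as the whole cause. A scaling factor moves all genes of a library alike, but the list's median lay at -0.53 from the median of 10000 lists matched on expression, GC content and length, of which 0 were as low (lowest -0.44), which argues against scaling as the whole cause. Ribosomal protein genes took 13.1 ± 0.816% of gene counts in CD4 T cells and 8.50 ± 0.191% in MAIT cells (SD, n = 3, 84 genes). The cause of this lower share stays open. It may lie in the cells or in a difference in RNA quality or sorting between the groups, which was not tested. The nuclear RNA MALAT1 was higher in the same libraries (0.353 ± 0.0446% of gene counts in CD4 T cells and 1.40 ± 0.813% in MAIT cells, with 2.34% in MAIT replicate 2).

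Cytotoxic genes differed between the CD4 T cell libraries, with 1166, 820 and 82.6 CPM for NKG7 and 924, 617 and 64.4 CPM for GZMH in replicates 1 to 3. NK cells could bring such RNA, but the NK transcripts TYROBP, FCER1G, KLRF1 and KLRD1 summed to 23.8 CPM in the library highest in NKG7 and 20.7 CPM in the lowest, a ratio of 1.15 against 14.1 for NKG7 itself. The sum was 39.9 CPM in the library between them, mostly from FCER1G (26.4 CPM), and TYROBP was at 0.903, 0.321 and 4.21 CPM, highest where NKG7 was lowest, which argues against NK cells as the whole source. CD8 T cells could as well, but CD8A was 0.150% of GZMH in the library highest in GZMH, and the gate on CD4 would remove both cell types. The granule genes GZMB (347, 228 and 26.7 CPM) and PRF1 (574, 386 and 83.2 CPM) moved as NKG7 did. So did CX3CR1 (155, 105 and 5.79 CPM) and FGFBP2 (294, 192 and 11.5 CPM), while CD4 was at 671, 607 and 611 CPM. The platelet gene PPBP moved the same way (146, 72.9 and 5.26 CPM). A shared technical difference between these libraries stays open, and so does a biological one. No biological explanation was tested because the labels give none.

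The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. In 1 of the 10 splits, the real one, the numbers were as large as observed for each of the 3 summaries. The real split gave 1103 genes and the highest other split 0 by edgeR (184 to 374 genes at an unadjusted p under 0.05, at most 25 by DESeq2 and 0 by voom), for differences of at least 2-fold 847 and 0, and for gene lists 18 and 11. Every other split puts both cell types in each group. Their difference then adds to the spread within groups and lowers the number of genes called. The other splits thus do not show what libraries without a difference would give. The lists did not fall to 0 with the genes, as camera with its preset correlation called 3 to 11 lists in the other splits. Whether those calls came from correlation between genes or from the cell types was not tested. A camera call at that setting therefore does not by itself show a difference between the cell types.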

How the results depend on the processing

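The alternatives with GC content and length offsets, without genes under an opposite-strand partner and with robust moderation were chosen after seeing the data. Pseudocount alternatives were not run, since the table holds counts.

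The number of genes, 1103, stayed within 1.5 times under DESeq2 size factors (1111), upper-quartile scaling (1166), at least 5 CPM in 3 libraries (1237) and voom (1161). It did so too in the table without mitochondrial, ribosomal protein, T cell receptor and immunoglobulin genes (894) and with GC content and length offsets (944). The table without genes under an opposite-strand partner (1084) and robust moderation (1069) also kept it in that range. The genes called were not all the same. With GC content and length offsets 747 of the 944 were among the 1103, and with voom 950 of the 1161, all with the same sign. The DESeq2 Wald test gave 2337 genes and 1605 at least 2-fold, and the cause was not tested. On simulated data with 200 changed genes 30.9% of its calls were false, against 4.12% for edgeR. Those data were drawn with dispersions from the edgeR fit, and the false share depends on how many genes change. It therefore does not give the share of false calls among the 2337. No filter gave 1668 and 1330, with 27374 genes tested in place of 14530. An adjusted p of 0.01 gave 305 genes, and a test against a 2-fold threshold gave 216 in place of 847, both stricter by construction. With 1 library left out, the ranges were 451 to 724 genes, 369 to 601 at least 2-fold, and 15 to 19 lists. These refits have fewer residual degrees of freedom, so lower numbers of genes do not by themselves show dependence on 1 library.

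With the replicate number as a block, 497 genes differed (235 higher, 262 lower) and 371 did so at least 2-fold, in place of 1103 and 847, and 478 of the 497 were among the 1103, all with the same sign. The lists stayed at 18. The labels do not say that equal numbers mark a pair, and correlations of residuals between libraries with equal numbers were 0.055, 0.047 and 0.013, under the 0.1 set for pairing. Between libraries with unequal numbers the correlations were lower, at -0.052 to 0.0023. Each equal-number value was the highest for its libraries. Residuals around a group mean sum to 0, however, so a value above 0 for equal numbers pushes the other values down. The lower values are thus no separate evidence for pairing, which the labels leave open. The block uses up residual degrees of freedom, so a lower number does not show by itself that pairing is wrong.

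The 18 lists stayed between 15 and 20 under fry (20) and the other alternatives run on lists, which leave out robust moderation. With an estimated correlation 5 were called, 4 higher and 1 lower, and the cause was not tested. Proliferation, interferon-stimulated and cytokine receptor genes lost their call although their estimates (-0.00066, -0.033 and 0.0033) lay under the preset 0.01. For those lists this argues against a higher correlation as the cause. Naive and central memory genes had an estimate of -0.035, and their camera adjusted p still rose from 6.59e-18 to 0.00758. A call lost with an estimated correlation thus does not by itself show correlation between the genes of a list. The other lists that lost their call had estimates above 0.01.

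Of the 151 named genes, 0 reversed in any refit, and the adjusted p of 0.01 and the test against a 2-fold threshold were not run on them one by one. Calls ended for 31 with the block, 10 with voom, 9 with GC content and length offsets, 2 each with upper-quartile scaling, no filter and the table without ribosomal and receptor genes, 1 with robust moderation, and 21 to 32 with 1 library left out. Calls were gained for 12 with DESeq2, 7 with no filter, 6 with at least 5 CPM, 4 with voom, 3 without genes under an opposite-strand partner, 2 each with DESeq2 size factors and upper-quartile scaling, 1 each with GC content and length offsets and robust moderation, and at most 5 with 1 library left out.

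Depth limits the genes with few counts. At 11949848 to 15782966 counts per library, a gene with 0 counts in a group is only bounded below 0.0784 CPM in CD4 T cells or 0.0748 CPM in MAIT cells, and 3 libraries per group left most simulated 2-fold changes uncalled (8% called by edgeR).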

Other observations

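The test of beta chain use in this part was chosen before its result was seen, and the other values were chosen after they were seen.

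T cell receptor gene use was read as a share of the counts on each class of segments, where close copies may share reads. TRAV1-2 took 1.42 ± 0.527% of alpha variable counts in CD4 T cells and 59.4 ± 2.85% in MAIT cells (SD, n = 3, 7469 to 12892 counts per library). The joining segment TRAJ33 took 1.42 ± 0.552% and 43.7 ± 9.53% of 290 to 583 TRAJ counts (log2 fold change 4.24, edgeR adjusted p = 0.0105). TRAJ12 took 0.985% and 4.72% and did not pass (edgeR adjusted p = 0.412). TRAJ20 took 2.17% and 1.15%. MAIT cells could use TRBV20-1 and the TRBV6 family more than CD4 T cells do, and these took 22.0 ± 1.69% of beta variable counts in CD4 T cells and 59.3 ± 4.71% in MAIT cells (53.9% to 62.4% per library), a difference of 37.3 percentage points. This is consistent with a biased beta repertoire among the sorted MAIT cells, though not for each member of the family. By level rather than share, TRBV6-4 (log2 fold change 5.15, edgeR adjusted p = 0.0013) and TRBV6-1 (1.05, 0.0174) were higher, TRBV6-6 was lower (-3.22, 0.00329), and TRBV6-5 (-0.75, 0.282) and TRBV20-1 (0.41, 0.454) did not pass. TRBV5-1 was lower (-5.25, 0.001).

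Among gamma chain segments, TRGV4 took 4.2% of TRGV counts in CD4 T cells and 21.9% in MAIT cells (log2 fold change 4.93, edgeR adjusted p = 0.0015), and TRGV10 had a log2 fold change of 2.30 (0.0107).

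Genes outside the rule, chosen after their values were seen, included CXXC5, a zinc finger gene, at 3.70 and 205 CPM (log2 fold change 5.79, edgeR adjusted p = 3.7e-05). The actin-binding genes TMSB10 (6645 and 2462 CPM, log2 fold change -1.43) and COTL1 (881 and 188 CPM, -2.23) were lower in MAIT cells. The log2 fold change of MALAT1, 1.93, became 1.16 after the correction for GC content and length (edgeR adjusted p = 0.0377).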
